A study of Danio rerio with 8 samples.

How the data were processed

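Hearts of zebrafish larvae at 4 days post-fertilization, exposed to 1 uM sorafenib or vehicle from 72 to 96 hours post-fertilization, were profiled on 8 Agilent one-colour arrays, 4 control and 4 sorafenib. Groups and replicate numbers come from the sample labels. Per the labels' protocols, total RNA of the heart was amplified and labelled with Cy3. Each scanner file deposited by the authors holds linear spot intensity in a processed signal, which the scanning software had background-subtracted, with flags per spot, and no normalization between arrays. Per the file headers the images were quantified with Feature Extraction 10.1.1.1, whereas the submitters' processing notes name Feature Extraction 8.0. The annotation build in the file headers is danRer5. A table of the whole series deposited by the authors holds log2 values for 21383 probes. Each column matched its own array best (r between 0.975 and 0.985 across probes), the column medians were 7.19 to 7.22, and every column had the same lowest and highest value, 5.66 and 16.60. Its log2 scale and direction follow from that match, while the centring and the filter that left these probes are not given in the sources used here. In it 1103 probes lie at the lowest value on every array and 5896 on at least 1, so it has a floor that shrinks folds of dim probes. It served as an alternative only, and a fit without those 1103 probes was added after seeing this.

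Each array had 45220 spots, of which 43803 were not controls. Control spots and 5 to 15 spots per array marked by the scanner as outliers were left out, 0 spots were saturated, and spots of one probe were averaged. The log2 processed signal minus the 75th percentile of the array was used. The median coefficient of variation of replicate probes was 3.66% to 6.45%, and the slope of the spike-in fit was 0.931 to 0.990. A probe entered where it was well above background on at least 4 of the 8 arrays, in either group. Probes were named through their RefSeq accessions in a RefSeq gene table of assembly GRCz12tu, which supplied names only. No coordinates are given because the builds differ. Of 43603 probes, 19212 carried a RefSeq accession and 15163 (34.78%) matched 10536 genes. Another 7356 probes carry Ensembl transcript numbers and stayed unnamed. The files used here have no column of gene names and no mean signal, which the plan had assumed, so the accession column and the median signal took their place. For the 3768 genes with more than 1 probe, the brightest stood for the gene. Probes of a gene could differ: those of ihhb ranged from -0.53 to 0.00 in log2 fold change, those of ddc from -1.23 to -0.48 and those of slc4a1a from 0.35 to 1.29. Probes of hmbsa ranged from 0.11 to 0.68, of ccn2a from 0.40 to 0.77, of pdia4 from 0.33 to 0.79 and of trpv6 from 0.16 to 0.52. Of the 20742 units tested, 8906 were named genes and 11836 unnamed transcripts. For 24 of them 1 group lay at the background limit on every array, and a fold is then given as a lower bound. The genes pdgfrb, nppb and vmhc, which were to be reported, had no probe matched by name and were not analysed here.

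Sorafenib was compared with control by limma 3.58.1 (lmFit and eBayes, R 4.3.3), with no covariates and Benjamini-Hochberg adjustment at 0.05. Fold changes are sorafenib minus control. The test, the alternatives, the rule for named genes and 37 gene lists were fixed before the data were examined. The lists cover sorafenib targets, ERK output, heart muscle, endothelium and other cell types of the heart, tissues that a dissected heart could carry, stress responses, metabolism, cell cycle and the circadian clock. Each list with 5 or more measured members was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Camera compares a list with the other genes, whereas fry asks whether a list's genes move on balance one way. A list's score is the mean of its genes per array, each relative to all arrays, and scores were compared by exact permutation tests. Counts adjusted over the list alone use limma p-values of that list's members only.

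The rule named up to 12 genes each way past the threshold, the 5 with the smallest p in a direction where fewer than 5 passed, 16 fixed genes, and members of each list. It left open what to name in a list that passed camera with no gene past the threshold. The 2 members with the smallest p were then taken, as for the other lists, after a first choice of 5. Members that passed over the list alone and some further genes were chosen after their values were seen. In all, 90 units were named by the rule and 22 afterwards.

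On simulated data with the spread of these arrays, 20742 genes and 200 changed genes, limma recovered 2% of genes changed 1.5-fold, 32% at 2-fold, 76% at 4-fold and 96% at 8-fold, with 3 false among 106 calls. A simulated changed list was called by all 3 list tests, and fry called 1 other list. Simulated genes were drawn independently, whereas estimated correlations within the real lists reached 0.726. The simulation therefore cannot show how the list tests behave with correlated genes. The arrays lay on 2 slides of 4, each scanned on its own and each holding 2 arrays of both groups, so the slide was fitted as a block and each slide alone. Within a slide, controls took positions 1 and 3 and sorafenib positions 2 and 4, so position and group cannot be told apart. Alternatives changed the normalization (quantile, median), the background correction (normexp), the starting values, the filter, the handling of probes, the blocks, the empirical Bayes prior, array weights, thresholds, the test (rank product) and the arrays, each left out in turn. Normexp as planned failed on sorafenib replicate 4, where a blemish raised the local background of some spots to as much as 1.64e+05. Local backgrounds marked by the scanner were therefore replaced by the array median, a step chosen after seeing the values. Normexp also added an offset of 50 to every signal. The median processed signal of an array was 7.65 to 14.2, so this offset by itself shrinks folds, most for dim probes. Leaving out sorafenib replicates 2 and 3 together, and fits with neural and liver scores as covariates, were also chosen after seeing the data.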

Results

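Gene expression was measured in the hearts of zebrafish larvae at 4 days post-fertilization. Larvae were kept in 1 uM sorafenib or in the vehicle alone from 72 to 96 hours post-fertilization. Sorafenib is an anticancer drug that inhibits RAF kinases and the receptors for vascular endothelial and platelet-derived growth factors. Cardiac side effects are known in patients. Total RNA from the heart was labelled with Cy3 and hybridised to 8 Agilent one-colour arrays, 4 per group, and the labels describe the 4 replicates of a group as separate experiments. Each array held 43603 different probes, and between 54.98% and 59.54% of its spots were well above background. The 75th percentile of the processed signal ranged from 85.1 to 154.6. Correlations of normalized log2 signal across probes were 0.947 to 0.985 between arrays of one group and 0.948 to 0.987 between arrays of different groups. The number of arrays limits the precision of every difference. The design implies 1 comparison, hearts exposed to sorafenib against hearts exposed to vehicle, and it asks which transcripts of the heart respond to the drug.

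In sorafenib-exposed hearts, markers of endothelium and endocardium were lower as a group, with a median log2 fold change of -0.39 over 28 measured genes. That call held in 2 list tests and was lost at adjusted p = 0.110 when the correlation between genes was estimated. Within that group 6 genes fell when adjusted over the list alone, among them the tight junction gene cldn5b (-0.95 ± 0.20, SE) and tek, which encodes the angiopoietin receptor (-0.71 ± 0.16). The transcript of stc1, a secreted glycoprotein that regulates calcium and phosphate, was lower by -1.33 ± 0.30 on the log2 scale. Higher transcripts included the collagen chaperone serpinh1b (+1.98 ± 0.32), the heme oxygenase hmox1b (+1.70 ± 0.33) and the cytokine feedback inhibitor socs3a (+1.70 ± 0.33), each of which rose when adjusted over its own list alone. No single gene passed an adjustment over all 20742 transcripts tested.

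**Figure D1:**
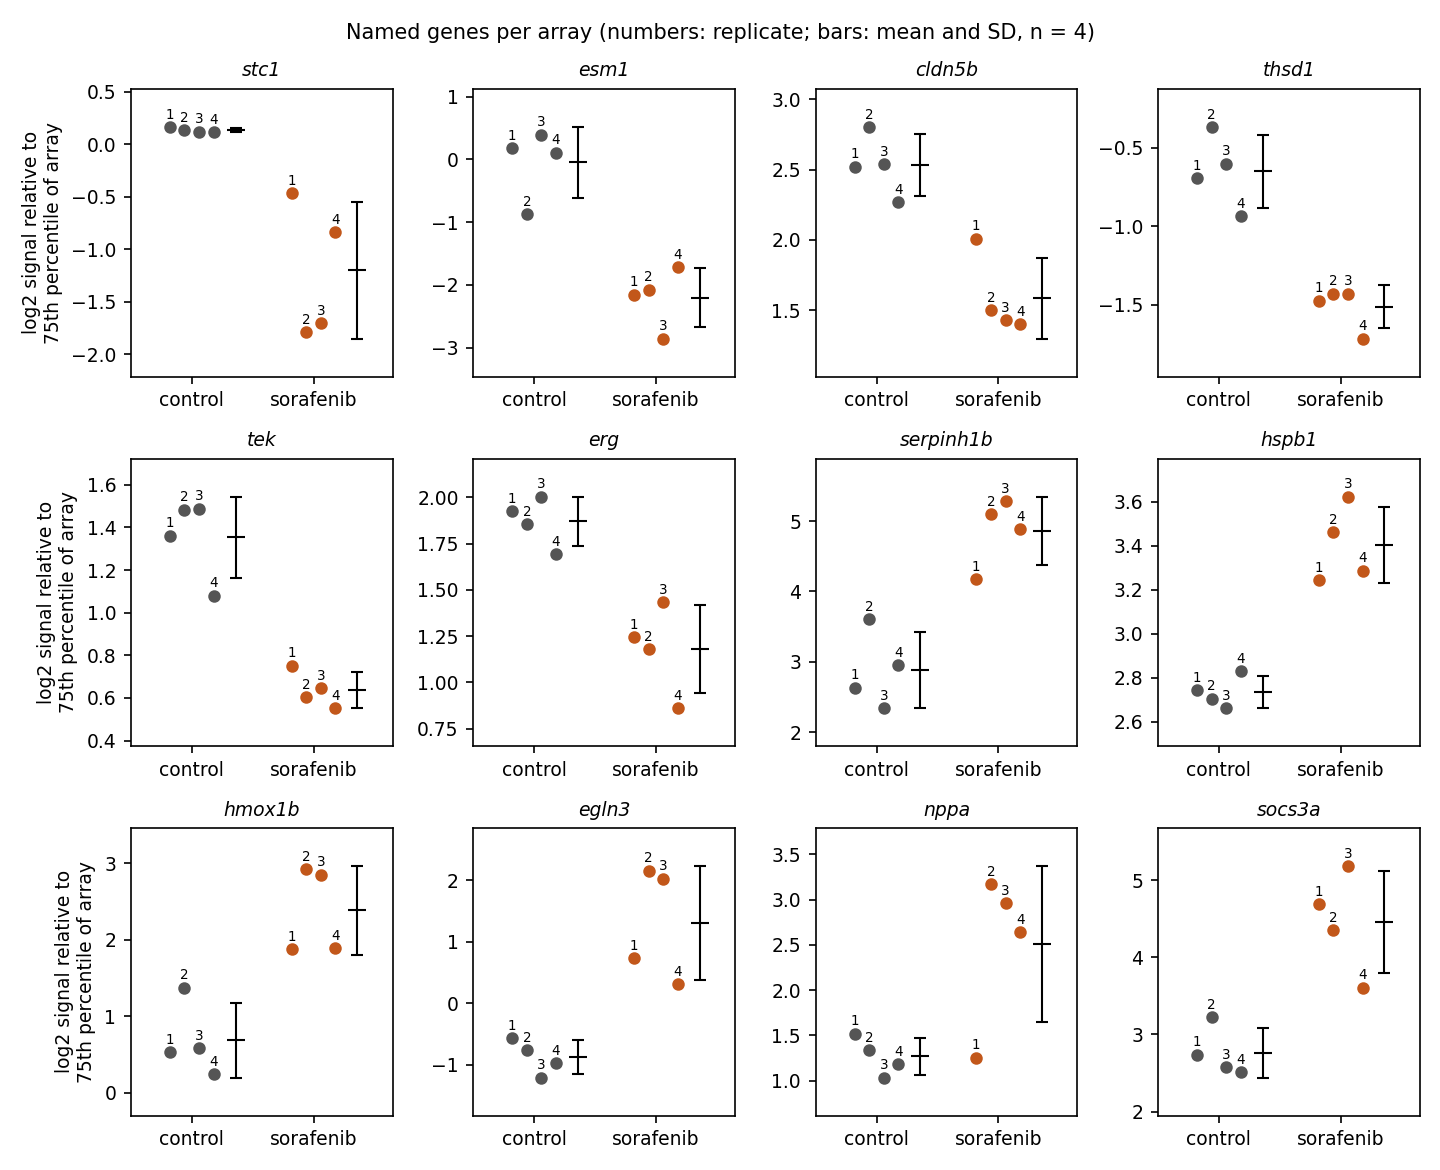
Normalized log2 signal relative to the 75th percentile of the array (y axis) for 12 named genes in control and sorafenib hearts (x axis). Each point is 1 array, numbered by replicate, and bars give the mean and SD of 4 arrays; the 4 stc1 values lie between 0.12 and 0.16 in controls and between -1.79 and -0.47 with sorafenib.

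The limma fit called 0 genes higher and 0 lower at a Benjamini-Hochberg adjusted p under 0.05, and so 0 genes at least 2-fold higher or lower. At an unadjusted p under 0.05 it held 1563 transcripts, 856 higher and 707 lower, where 1037 would be expected by chance. Of these, 186 were at least 2-fold higher and 132 at least 2-fold lower. The rank product, the other tool run, called 96 higher and 34 lower, but on simulated data with the same spread it made 99 wrong calls beside 104 right ones. The 4 sorafenib values lay entirely above or below the 4 control values for 865 transcripts, or 4.17%, where chance gives 2.86%. The smallest adjusted p was 0.0955, for slc4a2a, an anion exchanger gene. Its sorafenib level was at least 4.05-fold that of controls, in which the probe was not well above background on any array. Its log2 fold change was +0.38 after normexp, whose offset of 50 shrinks the folds of dim probes here and below. Here and below, "at least" compares the mean of the brighter group with the lowest signal measurable on the arrays of the other. The zinc finger gene zmat1 followed at +1.45 ± 0.18 (adjusted p = 0.104), or +0.74 after normexp. Among lower transcripts with a name, esm1, an endothelial proteoglycan gene, had the smallest p, at -2.15 ± 0.33 (adjusted p = 0.228), or -1.10 after normexp. The other 3 higher and 4 lower transcripts among the 5 with the smallest p in each direction have no gene name here. Without control replicate 3, slc4a2a alone passed (adjusted p = 0.0117), and under other settings of limma up to 18 genes were called higher and 13 lower, both with array weights in the fit.

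The level of stc1 averaged 0.13 ± 0.02 (SD, n = 4 arrays) in controls and -1.20 ± 0.65 with sorafenib, with no overlap between the groups. The difference had an unadjusted p of 0.00134 in limma and an adjusted p of 0.391 over all transcripts. Adjusted over the list alone, among 6 measured stanniocalcins and calcium regulators, its p was 0.00801. The published study singled out stc1 on these samples, so this count is not independent evidence. The value was -1.28 on slide 1, -1.39 on slide 2 and -1.33 with the slide as a block. It was smaller in size after normexp (-0.67 with either scaling), whose offset by itself shrinks folds. It was also smaller in the series table (-0.91) and with the neural score as a covariate (-0.87). The 2 lowest sorafenib values, -1.79 and -1.70, came from replicates 2 and 3, which also had the lowest scores of neural markers. Without both of these arrays, an alternative chosen after seeing the scores, the stc1 log2 fold change was -0.79.

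Of the 28 endothelial and endocardial markers measured, 25 had a negative log2 fold change, 10 of them at an unadjusted p under 0.05. Adjusted over the list alone, thsd1 (-0.86), cldn5b (-0.95), tek (-0.71), fli1rs (-0.66), erg (-0.69) and etsrp (-0.72) fell, and 0 genes of the list passed over all transcripts. After normexp thsd1 stood at -0.39 and etsrp at -0.32. The genes erg, etsrp and fli1rs encode ETS transcription factors of the endothelial lineage, and thsd1 encodes a membrane protein of endothelial cells. Among members without a change past a test, dll4 stood at -0.42, the flow-responsive factor klf2a at +0.36 and the venous receptor ephb4b at +0.19. The most abundant members of the list were s1pr1 (-0.22), klf2a and klf2b (-0.07), so the genes that fell when adjusted over the list alone were less abundant ones. The list passed camera with the preset correlation (adjusted p = 3.34e-08) and fry (adjusted p = 0.00797). It did not pass at adjusted p = 0.110 with an estimated correlation. Its mean score was 0.20 ± 0.05 (SD, n = 4) in controls and -0.20 ± 0.07 with sorafenib, separated on every array. An exact permutation test gave p = 0.0286, two-sided, which is the smallest that 4 against 4 unpaired arrays allow. Adjusted over 37 lists, this p was 0.453. The mean log2 fold change of the list was -0.39 on slide 1, -0.40 on slide 2 and -0.40 with the slide as a block. It was -0.35 without sorafenib replicates 2 and 3, and -0.36 with neural and liver scores as covariates.

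**Figure D2:**
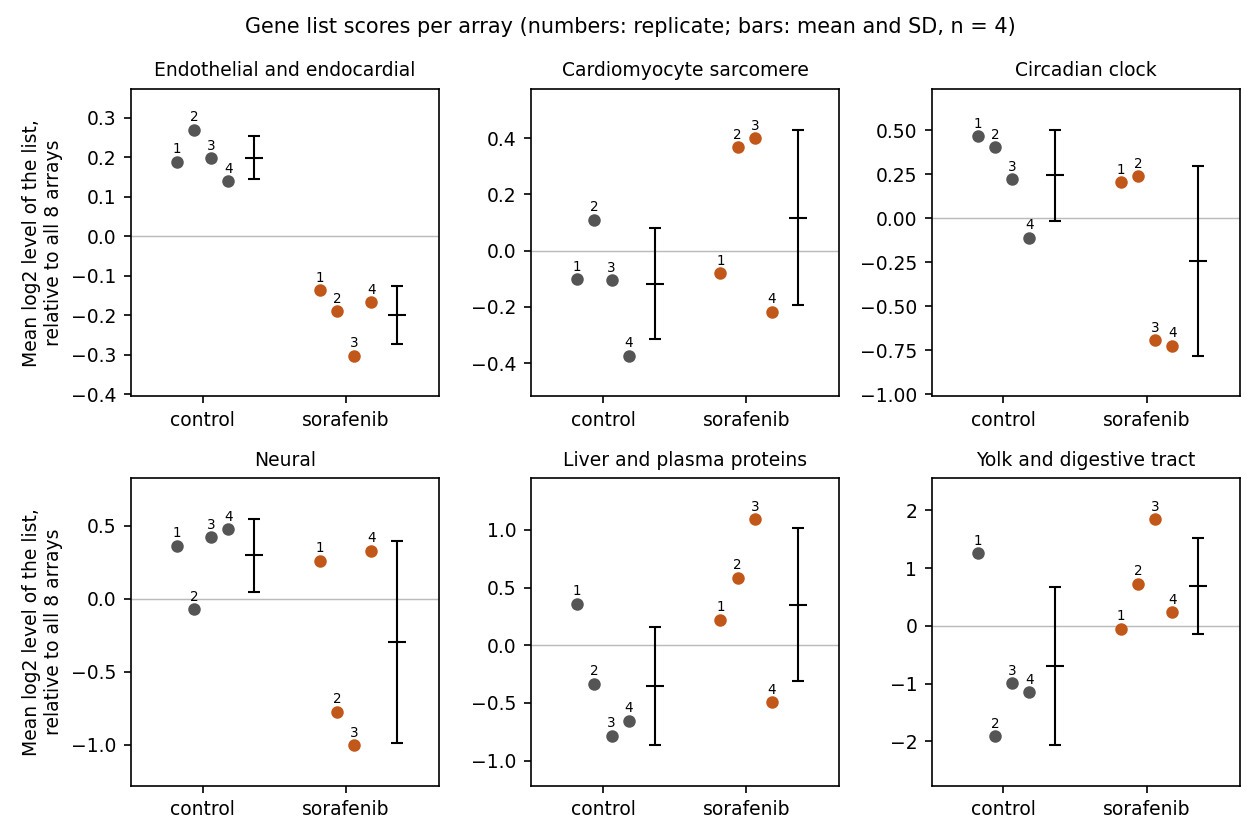
Mean log2 level of 6 gene lists per array, relative to the mean of all 8 arrays (y axis), in control and sorafenib hearts (x axis). Points are arrays, numbered by replicate, and bars give the mean and SD of 4; endothelial scores separate the groups completely, while sorafenib replicates 2 and 3 stand lowest for neural markers, at -0.77 and -1.0.

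Markers of tissues that lie near the heart also differed. All 46 neural genes measured had negative values, with a median of -0.58 (camera adjusted p = 3.42e-10). The tubulin genes tubb5 (-0.90) and tubb2 (-1.07) had the smallest p. Liver and plasma protein genes were higher in 32 of 34 cases, with a median of +0.73 (camera adjusted p = 7.36e-10), including cp, which encodes ceruloplasmin (+1.16), and the complement gene c3a.2 (+1.57). All 19 yolk and digestive tract genes were positive, with a median of +1.47 (camera adjusted p = 2.8e-08), among them glucagon gene gcga (+1.47) and carboxypeptidase cpa4 (+1.86). The groups overlapped in the score of this list, at 1.27 in control replicate 1 and -1.91 to -0.99 in the other controls, against -0.05, 0.73, 1.85 and 0.24 in sorafenib replicates 1 to 4, and its mean was +0.66 on slide 1 and +2.11 on slide 2. For each of these 3 lists the call was lost, at adjusted p = 0.559 with an estimated correlation. The eye and lens list had a median of +0.62 over 12 genes (camera adjusted p = 0.0105, and 0.559 with an estimated correlation). Its mean was +1.19 on slide 1 and +0.09 on slide 2 (adjusted p = 0.430). Its retinal member rlbp1b rose when adjusted over the list alone (+0.75), and the cone transducin gnat2, well above background on 3 of 4 control arrays, stood at +2.09. Over the alternatives rlbp1b ranged from +0.22 to +0.87 and gnat2 from +0.60 to +2.65. Skin and pharyngeal epithelium genes had a median of +0.16 (camera adjusted p = 0.0105, and adjusted p = 0.645 with an estimated correlation), with grhl2b at +0.62 and aep1 at +0.45. The neural score was -0.77 and -1.0 in sorafenib replicates 2 and 3, and 0.26 and 0.33 in replicates 1 and 4, where controls ranged from -0.07 to 0.47. The liver score of replicates 2 and 3 was 0.59 and 1.09, against -0.78 to 0.36 in controls. Without sorafenib replicate 3 the mean of the neural list moved from -0.59 to -0.36 and that of the liver list from +0.71 to +0.46. The eye and lens call was lost without sorafenib replicate 2 (mean +0.29, adjusted p = 0.0597) or 4 (+0.67, adjusted p = 0.0680), in the series table (+0.15, adjusted p = 0.0807), and among the 7 members well above background on all arrays (+0.31, adjusted p = 0.113). The skin call was lost without control replicate 4 (+0.09) or sorafenib replicate 2 (+0.10) or 3 (+0.10).

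Heat shock and stress lists were higher by camera with the preset correlation. The cytosolic heat shock list had 23 of 29 members positive, with a median of +0.18 (adjusted p = 0.00131). It also holds the collagen chaperone gene serpinh1b, whose protein is not cytosolic. Adjusted over the list alone, serpinh1b (+1.98), the small heat shock protein gene hspb1 (+0.67) and the co-chaperone gene dnajb1b (+0.90) rose. Antioxidant genes had a median of +0.23 with 34 of 39 positive (adjusted p = 9.83e-05), and hmox1b rose when adjusted over the list alone, while the glutathione synthetase gss stood at +0.88, or +0.16 after normexp, its probe lying at the floor of the series table on every array. Endoplasmic reticulum chaperones had a median of +0.23 with 33 of 40 positive (adjusted p = 0.000176), led by pdia4 (+0.79) and hspa5 (+0.77). The integrated stress response list had 30 of 39 positive and a median of +0.18 (adjusted p = 0.00133), with cebpb at +1.15 and gadd45ba at +1.05. In the ferroptosis list hmox1b and hspb1 were the 2 of 20 members that rose adjusted over the list alone, and the median was +0.20 (adjusted p = 0.0105). The p53 and apoptosis list had a median of +0.10 (adjusted p = 0.0105), with mcl1b at +0.67 and gadd45bb at +0.73. For each of these 6 lists the call was lost, at adjusted p = 0.559 with an estimated correlation. The scores of all 6 were higher in sorafenib replicates 2 and 3 than in every control array, as the liver scores were, and without both arrays none of the 6 passed. In sorafenib replicate 1, whose neural and liver scores lay within the control range, the ferroptosis (0.19), integrated stress response (0.20) and p53 (0.10) scores also lay above every control array, while the other 3 did not. Leaving out control replicate 1 ended the calls of the ferroptosis list (mean +0.20, adjusted p = 0.0556) and the p53 list (+0.14, adjusted p = 0.0556), and the p53 call was also lost without control replicate 4 (+0.11) and under 4 other planned scalings or starting values. Without sorafenib replicate 3 the antioxidant mean was +0.17 and the chaperone mean +0.13, from +0.26 and +0.23.

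Among inflammatory genes, socs3a (+1.70) and socs3b (+1.22), feedback inhibitors of cytokine signalling, rose when adjusted over the leukocyte list alone. That list had a median of +0.28 with 21 of 30 positive (camera adjusted p = 0.00131, and adjusted p = 0.559 with an estimated correlation). Heart muscle genes of the sarcomere had 26 of 31 positive values and a median of +0.23 (camera adjusted p = 0.00148, and adjusted p = 0.574 with an estimated correlation), with xirp1 at +0.67 and actn2b at +0.81. All 6 epicardial genes were positive, with a median of +0.30 (camera adjusted p = 0.00338), led by wt1b (+0.75) and tgm2b (+0.47). The epicardial call gave adjusted p = 0.559 with an estimated correlation. Both lists were highest in sorafenib replicates 2 and 3 (epicardial 0.39 and 0.56, sarcomere 0.37 and 0.40), the arrays apart in neural and liver markers, and replicates 1 and 4 lay within the control range. With neural and liver scores as covariates the epicardial mean was +0.04 and the sarcomere mean -0.06. The same fit gave means of +0.03 for xenobiotic metabolism, -0.06 for the leukocyte list, -0.12 for oxidative phosphorylation, -0.02 for cholesterol synthesis and -0.08 for skin, and of +0.06 each for the heat shock, integrated stress response and p53 lists, none past camera. With the liver score alone, oxidative phosphorylation was called lower (-0.14, adjusted p = 0.0488). Leukocyte (0.56 and 0.42) and xenobiotic (0.35 and 0.46) scores were also above every control array in sorafenib replicates 2 and 3 only, and socs3b stood at +0.74 with both covariates. Oxidative phosphorylation genes had a median of +0.16 with 61 of 68 positive (camera adjusted p = 0.00148, and adjusted p = 0.674 with an estimated correlation). The 2 members of that list with the smallest p pointed apart, the ADP/ATP carrier slc25a4 at -0.47 and sdhdb at +0.28. Cholesterol synthesis genes had a median of +0.25 (camera adjusted p = 0.00288), with pmvk at +0.49 (+0.12 after normexp, and at the floor of the series table on every array) and mvda at +0.51. Xenobiotic metabolism genes had a median of +0.26 (camera adjusted p = 0.00148), with cyp1c1 at +0.81 and cyp2k18 at +1.19. Circadian clock genes were lower, with a median of -0.28 and 18 of 22 negative (camera adjusted p = 0.00335), and the period genes per2 and per1b stood at -2.36 and -0.56. These last 3 lists each gave adjusted p = 0.559 with an estimated correlation. The clock list had a mean of -0.21 on slide 1 and -0.76 on slide 2, and its call was lost without sorafenib replicate 4 (-0.33, adjusted p = 0.0924) and with array weights (-0.31, adjusted p = 0.0518). Without a single array the calls of 3 more lists ended: the leukocyte list without sorafenib replicate 2 (mean +0.19), cholesterol synthesis without sorafenib replicate 3 (+0.11), and oxidative phosphorylation without control replicate 4 (+0.08), sorafenib replicate 1 (+0.07) or sorafenib replicate 3 (+0.06). The sarcomere mean went from +0.24 to +0.14 without sorafenib replicate 3 and to +0.15 without control replicate 4 or sorafenib replicate 2.

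**Figure D3:**
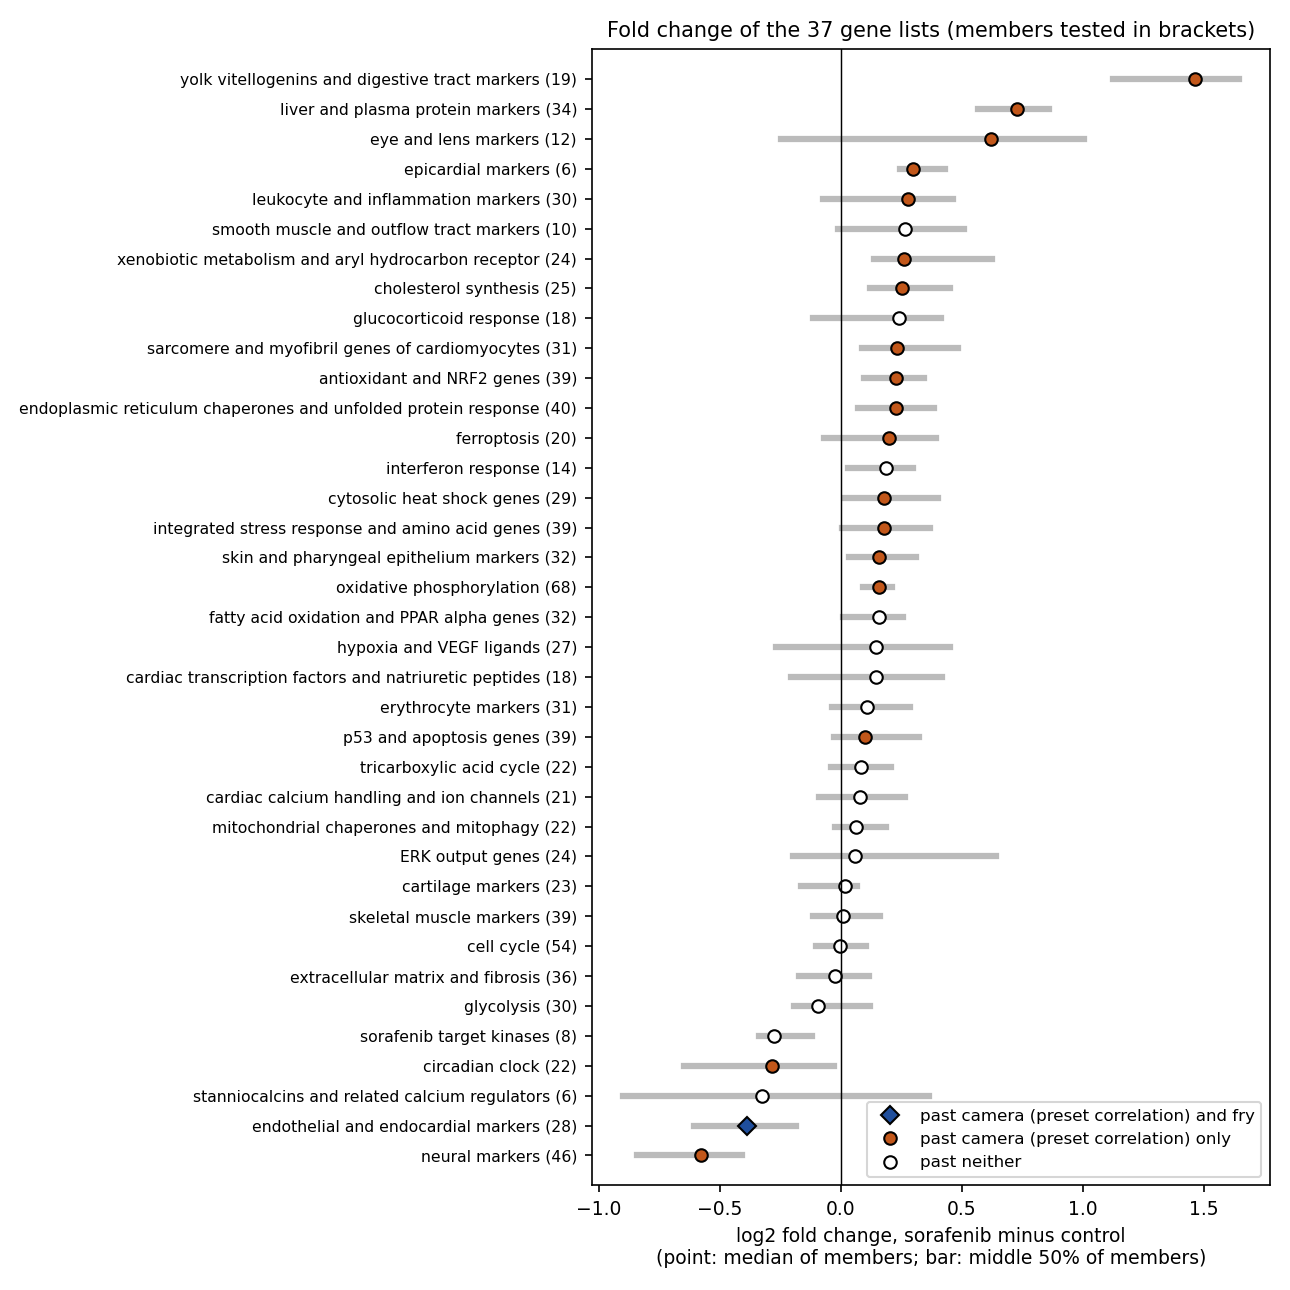
Log2 fold change, sorafenib minus control (x axis), of the 37 gene lists fixed beforehand (y axis, members tested in brackets). Points are medians and bars span the middle 50% of members; the endothelial list alone passed both camera with the preset correlation and fry, at a median of -0.39.

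The remaining 18 lists did not pass camera. The means of all but the stanniocalcin list changed by more than 1.5 times in size when some single array was left out. Kinases that sorafenib inhibits had a median of -0.28 over 8 genes (adjusted p = 0.127) and a mean of -0.23, which was -0.13 without control replicate 2 and -0.06 after normexp, with kdr at -0.59 (well above background on 3 control arrays and 1 sorafenib array, and -0.013 after normexp), ret at -0.24, flt4 at -0.32, pdgfra at -0.39 (+0.04 after normexp and +0.01 in the series table), braf at -0.31 and raf1a at +0.13. The probes of kdrl, flt1 and kita were not well above background on any array. Genes downstream of the kinase ERK had a median of +0.06 (adjusted p = 0.186), with 7 higher and 2 lower of 24 at an unadjusted p under 0.05. The immediate early genes junba (+1.35) and fosab (+1.11) had the smallest p, and the feedback regulators dusp6 and spry4 stood at +0.09 and +0.29. In the hypoxia list, with a median of +0.15 (adjusted p = 0.193), the prolyl hydroxylase gene egln3 rose when adjusted over the list alone (+2.19 ± 0.41, and +1.37 with neural and liver scores as covariates), while pfkfb4a stood at -0.75. Extracellular matrix genes showed a median of -0.02 and a mean of +0.04, or -0.0085 in the series table (adjusted p = 0.509). Yet the matricellular genes ccn1 (+1.08) and ccn2a (+0.77) rose adjusted over the list alone, with another probe of ccn2a at +0.40. Cardiac transcription factors and natriuretic peptides had a median of +0.15 (adjusted p = 0.352). Their member nppa, the atrial natriuretic peptide, stood at +1.24 ± 0.38 (adjusted p = 0.559 over all transcripts), with the replicate 1 value of sorafenib inside the control range, and gata6 stood at +0.64. Stanniocalcins and calcium regulators had a median of -0.33 (adjusted p = 0.231), with the calcium channel trpv6 at +0.52 beside stc1.

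Other lists of heart and blood cells did not pass camera either. Cardiac calcium handling genes had a median of +0.08 and a mean of +0.11, or -0.02 in the series table (adjusted p = 0.388), with the connexin gja1b at -0.47 and atp1b1a at +0.45, and the myosin light chain myl7 stood at +0.26. Smooth muscle genes had a median of +0.27 (adjusted p = 0.0525), with tagln at +0.69 and acta2 at +0.80. Erythrocyte genes had a median of +0.11 (adjusted p = 0.124), with hmbsa at +0.68 and slc4a1a at +1.29. Other probes of hmbsa and slc4a1a stood as low as +0.11 and +0.35. The gene gata1a, well above background on 3 of 4 control arrays, stood at +0.56, or +0.09 without control replicate 2. The interferon list had a median of +0.19 (adjusted p = 0.186) and a mean of +0.15, which was +0.03 without sorafenib replicate 2 and -0.20 with neural and liver scores as covariates, with irf9 at +0.65 and psmb9a at -0.32, or +0.0069 after normexp. Glucocorticoid response genes had a median of +0.24 (adjusted p = 0.0911), with cebpd at +0.88 and dusp1 at +0.83. Among metabolic lists, fatty acid oxidation had a median of +0.16 (adjusted p = 0.0610), with fabp7a at -0.89 and acaa1 at +0.59. The gene fabp7a is also in the neural list and stood at -0.29 with neural and liver scores as covariates, where acaa1 stood at +0.31. The tricarboxylic acid cycle had a median of +0.08 (adjusted p = 0.20), with idh3b at +0.36 and suclg1 at +0.33, and glycolysis had -0.09 (adjusted p = 0.467), with pklr at +0.92 and pgam1b at -0.47. The list of mitochondrial chaperones and mitophagy had a median of +0.06 (adjusted p = 0.350). Its members with the smallest p were gabpa, which is not a chaperone gene, at -0.49 and hspd1 at +0.52. Skeletal muscle had a median of +0.01 and a mean of +0.04, or -0.02 in the series table (adjusted p = 0.422), with cacng1a at +0.59 and mstnb at +0.45. Cell cycle genes had a median and a mean just below 0 although camera set their direction upward (adjusted p = 0.608), and a mean of +0.05 with the median of each array as scaling, with ccne1 at +0.53 and aurka at +0.44. Cartilage had a median of +0.02 and a mean of -0.03, or +0.02 with the median as scaling (adjusted p = 0.665), with matn3a at -0.67 and ihhb at -0.53.

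Of the 37 lists, 19 passed camera with the preset correlation, 16 higher and 3 lower, 0 with an estimated correlation and 1, the endothelial list, by fry. Without sorafenib replicates 2 and 3 together, 2 lists were higher (yolk and digestive tract, eye and lens) and 2 lower (endothelial, circadian clock). On slide 1 alone 12 lists were higher and 2 lower, and on slide 2 alone 15 and 3. The heat shock, cholesterol synthesis, sarcomere, epicardial, xenobiotic and clock calls were lost on slide 1 alone, and the eye, ferroptosis, p53 and skin calls on slide 2 alone.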

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

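No test in this part was chosen after its result was seen. The genes covered do include those named after their values were seen, among them fli1rs, ephb4b and ren. In 19 of 292 groups of 4 arrays the highest or lowest array stood apart from the others, its gap to the nearest taking more of the group's range than Dixon's critical value, where chance gives about 15. Among single genes, gata1a was at -5.08 in control replicate 2 against -3.27 to -3.10 in the others (gap share 0.914). The clock gene per2 was at -0.91 in control replicate 4 against 0.94 to 1.15 (0.9). The endothelial genes thsd1, cldn5b, fli1rs and ephb4b stood apart in 1 array each. These were thsd1 in sorafenib replicate 4 (-1.72 against -1.47 to -1.43, share 0.843), cldn5b in sorafenib replicate 1 (2.01 against 1.40 to 1.5, share 0.834), fli1rs in control replicate 4 (1.06 against 1.25 to 1.29, share 0.857) and ephb4b in control replicate 1 (-0.64 against -0.23 to -0.18, share 0.881). For rlbp1b of the retina, control replicate 1 was at -2.22 against -2.61 to -2.58 (0.93). In the same array the thiolase gene acaa1 was at 2.5 against 1.86 to 1.94 (0.875). In control replicate 2, the fatty acid binding protein gene fabp7a was at 5.57 against 6.13 to 6.24 (0.84) and the glycolytic gene pgam1b at 3.33 against 3.94 to 4.02 (0.88). In sorafenib replicate 4, idh3b was at 3.38 against 3.93 to 3.95 (0.963). The renin gene ren was at -6.48 in sorafenib replicate 3 against -5.26 to -5.08 (0.875), where its probe was not well above background on any array.

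Among list scores, that of cardiac transcription factors was -0.27 in control replicate 4 against 0.0023 to 0.05 in the other controls (0.841). The erythrocyte score was -0.46 in control replicate 2 against 0.06 to 0.11 (0.918), and 0.29 in sorafenib replicate 3 against -0.06 to -0.01 (0.853). Sorafenib replicate 4 stood below the other sorafenib arrays for ferroptosis (-0.13 against 0.17 to 0.21, share 0.875), for the integrated stress response (-0.21 against 0.20 to 0.26, share 0.869) and for the tricarboxylic acid cycle (-0.25 against 0.10 to 0.17, share 0.844). The integrated stress response was also lowest in control replicate 4, at -0.26 against -0.07 to -0.05 (0.942).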

How the results depend on the processing

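Leaving out sorafenib replicates 2 and 3 together, the repair of scanner-marked backgrounds before normexp and the series table without probes at its floor were chosen after the results were seen; the other alternatives were planned. For genes (higher, lower), limma called 2 and 0 with quantile normalization, 1 and 0 with the median of each array, 1 and 0 after normexp, 2 and 2 after normexp with quantile normalization (1 at least 2-fold higher), 3 and 5 from the series table (1 at least 2-fold higher), 2 and 2 from that table without the 1103 probes at its floor on every array (1 at least 2-fold higher), 2 and 0 with the mean of a gene's probes, 1 and 0 at adjusted p under 0.1, 0 to 1 and 0 with one array left out, and 18 and 13 with array weights (18 and 12 at least 2-fold). The rank product called 96 and 34 (95 and 34 at least 2-fold). Other settings gave 0 and 0, with 714 to 4726 transcripts at an unadjusted p under 0.05 over all. Named calls of limma at adjusted p under 0.05 included slc4a2a in 5 settings, zmat1 in 4 and ddc in 2, besides unnamed transcripts. The gene called at adjusted p under 0.1 was slc4a2a as well, and the rank product called slc4a2a and zmat1. The cause was not tested. The stc1 value stayed between -1.61 and -0.67 (adjusted p 0.0536 to 1), and the endothelial mean between -0.42 and -0.26 (camera adjusted p 4.46e-11 to 5.24e-06). List counts (higher, lower) were 13 to 19 and 2 to 3 with one array left out, 0 and 0 with an estimated correlation, 0 and 1 by fry, and 2 and 2 without both arrays, where fewer samples entered. Before the repair, normexp put the 10th percentile of sorafenib replicate 4 at 9.13 (5.79 after) and gave 2 and 15. The labels tie the replicate numbers to no shared clutch or day, and deviations of same-numbered arrays correlated at 0.265, 0.426, 0.0352 and 0.696, so the arrays were not treated as pairs because the value of replicate 3 was near 0. Yet all 4 control arrays and 3 of 4 sorafenib arrays matched their own number best, which is a hint of pairing from the data. Arrays of the same number also lay at neighbouring positions of one slide, so the layout pairs them too. With the replicate number as a block, 0 genes and 17 and 3 lists were called, and stc1 stood at -1.33. That fit held 2794 transcripts at an unadjusted p under 0.05, against 1563 without the block, and its smallest adjusted p in limma was 0.295.

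Signs turned for 5 named genes and did not turn for 107 (gss and pmvk being at the floor of the series table). They also turned for lists, some with means near 0. Without sorafenib replicates 2 and 3 they turned for lists with larger means in the main fit as well. These included leukocyte (+0.32), sarcomere (+0.24), skin (+0.16), interferon (+0.15) and oxidative phosphorylation (+0.14). The cause was not tested. With the median of each array, cartilage was 0.023 and cell cycle 0.054. After normexp, pdgfra was 0.037 and psmb9a 0.0069. In the series table, pdgfra was 0.011, cardiac calcium handling -0.019, extracellular matrix -0.0085 and skeletal muscle -0.016, and without the floor these were the same but for calcium handling, at -0.020. With array weights, cell cycle was 0.023. With one array left out, cell cycle ranged from -0.044 to 0.066, cartilage from -0.071 to 0.022, erythrocyte genes from -0.041 to 0.15, skeletal muscle from -0.00083 to 0.10, raf1a from -0.015 to 0.30 and dusp6 from -0.0074 to 0.25. Without both arrays, raf1a was -0.090, myl7 -0.22, cartilage 0.030, cardiac calcium handling -0.0096, cardiac transcription factors -0.0097, extracellular matrix -0.032, fatty acid oxidation -0.057, interferon -0.17, leukocyte genes -0.0099, mitochondrial chaperones -0.038, oxidative phosphorylation -0.0031, sarcomere -0.031, skeletal muscle -0.041, skin -0.024 and the tricarboxylic acid cycle -0.036. All of these had an adjusted p above 0.05 there. Camera calls were also lost for the skin and p53 lists with quantile normalization, for p53 after both normexp settings, for p53, cholesterol synthesis and eye in the series table, for p53 and eye in that table without its floor, for eye among probes well above background on all arrays, and for the clock with array weights. In 28 cases a list not called in the report passed camera under an alternative, most often smooth muscle and fatty acid oxidation, and once the target kinases, lower with every probe on its own (adjusted p = 0.0321). Signal near background limits slc4a2a, prlrb and ren, whose probes were not well above it in 1 group, and kdr, gja4 and opn1mw1, well above it on only some arrays.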

Other observations

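The tests on endothelial, neural and liver, and clock lists in this part, the fits with list scores as covariates, and the genes named in this paragraph and as clock genes below were chosen after the results were seen; the counts over other splits were planned. None of these genes passed limma over all transcripts, though prlrb, ren and opn1mw1 were called by the rank product, and edn1, prlrb and ddc passed limma with array weights. The ddc gene also passed in the series table (-0.42, adjusted p = 0.0492), though not without the probes at that table's floor. The endothelin gene edn1, a vasoconstrictor peptide, stood at +1.2 ± 0.24 (SE, limma adjusted p = 0.307), with no overlap between the groups. The connexin gene gja4 stood at -1.29 ± 0.26 (adjusted p = 0.315), or -1.53 to -0.09 over the alternatives, and was well above background on 1 of 4 sorafenib arrays. Renin, the enzyme that starts the angiotensin cascade, was well above background on all 4 control arrays and on 0 sorafenib arrays, so ren was at least 1.89-fold lower with sorafenib (adjusted p = 0.272). Over the alternatives the log2 fold change of ren ranged from -2.12 to -0.12. The growth factor vegfd stood at -0.71 (adjusted p = 0.616) and the ETS factor etv5b, an output of fibroblast growth factor signalling, at -0.53 (adjusted p = 0.607). The prolactin receptor gene prlrb was at least 2.48-fold higher with sorafenib (adjusted p = 0.255), its probe being not well above background on any control array. Its log2 fold change ranged from +0.22 to +2.35 over the alternatives. The decarboxylase gene ddc stood at -1.23 (adjusted p = 0.307), with another of its probes at -0.48, and the tryptophan hydroxylase gene tph1b at -1.19 (adjusted p = 0.265). The green cone opsin opn1mw1 stood at +2.13 (adjusted p = 0.600), or +0.37 to +2.65 over the alternatives, well above background on 1 control and 3 sorafenib arrays.

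The real split called 0 genes, so all 35 splits of the 8 arrays into 4 and 4 reach it whatever the data and this count decides nothing; the highest other split called 7. For transcripts at an unadjusted p under 0.05, 9 of the 35 splits reached the real 1563, and the highest other gave 5020. For lists past camera with the preset correlation, 5 of the 35 splits reached the real 19, and the highest other gave 20. For lists past fry, 3 of the 35 reached the real 1, and the highest other gave 9. Chance was thus not excluded for the counts of transcripts and of lists. The split of control replicate 1 with sorafenib replicates 1, 2 and 3 against the rest gave the 7 genes, the 5020 transcripts, 20 lists by camera and the 9 by fry. It differs from the real split only in control replicate 1 and sorafenib replicate 4, so it is not independent of the groups. Those 4 arrays had the highest liver scores (0.36, 0.22, 0.59 and 1.09, against -0.78 to -0.33 in the rest). The split by slide called 3 genes, and with the slide as a block the real comparison called 0 genes, 16 lists higher and 3 lower.

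Lower endothelial markers are a candidate response to the drug, as a hypothesis, though their camera call was lost at adjusted p = 0.110 with an estimated correlation. The most abundant members, s1pr1 (-0.22), klf2a (+0.36) and klf2b (-0.07), did not move clearly with the list, so its fall rests on less abundant members. The neural and liver scores do not account for the whole fall, since the mean of the list was -0.36 with both as covariates (camera adjusted p = 6.77e-05 at the preset correlation). Other carried tissue was not modelled. The yolk and digestive list stayed at +0.55 in that fit, so carried tissue as a whole is not excluded. A larger share of muscle cells would lower other heart cell types alike. The mean score of epicardial, smooth muscle, leukocyte and erythrocyte lists minus the endothelial score was higher with sorafenib by 0.66 and separated the groups (exact permutation p = 0.0286, the smallest possible). The endothelial score alone does so at the same p, so this adds no support. The epicardial and leukocyte scores exceeded every control array in sorafenib replicates 2 and 3 only. With neural and liver scores as covariates, means were +0.04 (epicardial), -0.006 (smooth muscle), -0.06 (leukocyte) and +0.04 (erythrocyte). These lists thus did not fall as the endothelial list did. Scaling is argued against by a mean of -0.41 with quantile normalization and -0.34 with the median of each array. The value nearest to 0 was -0.26 after normexp, which changes the background correction and adds an offset that shrinks folds. No other split moved the list by more than 0.26 in size. Because the scores separate the groups completely, the real split had to move the list most. The splits thus add no support and say nothing on scaling. Array position within the slide cannot be told apart from the group, 5 of the 28 genes are in another list, and fewer endothelial cells or lower expression per cell were not tested.

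Neural markers were lower and liver, yolk and digestive markers higher, and neighbouring tissue carried in different amounts on each array may explain it, as 2 of 4 sorafenib arrays lay below every control array for neural markers while the other 2 lay within the control range. The most abundant members moved partly with their lists, with tubb5 at -0.90, slc1a2b at -0.63 and fabp7a at -0.89 for neural tissue, fabp10a at +0.72, rbp4 at +0.12 and apoa4b.1 at -0.05 for liver, and fabp1b.1 at +1.18, ctrl at +1.5 and prss1 at +1.60 for the digestive tract. Of the 46 neural, 34 liver and 19 digestive genes, 44, 34 and 16 were well above background on all arrays, and 2, 2 and 0 are in another list. With both scores as covariates 1 list stayed higher, yolk and digestive tract (+0.55), and 1 lower, the endothelial list; antioxidant and chaperone means were then -0.03 and -0.02, the ferroptosis mean went from +0.22 to +0.12 and its call was lost, and serpinh1b (+1.66 ± 0.30, SE) and hmox1b (+1.18 ± 0.21) were less reduced. An effect of the drug on those tissues stays open, as untested.

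Clock genes were lower, and time of day or light at collection differing between arrays is a candidate explanation. The mean of the list on slide 2 minus that on slide 1 was -0.55. Sorafenib scores were 0.20 and 0.24 on slide 1 and -0.69 and -0.72 on slide 2. Control scores were also lower on slide 2, at 0.46 and 0.40 on slide 1 and 0.22 and -0.11 on slide 2. Within each slide, both sorafenib arrays lay below both controls. The light-induced gene per2 stood at -2.36 ± 0.93 (SE), the flavoprotein gene cry5 at -1.97 ± 1.14 and nr1d1 at -1.17 ± 0.50, none past limma over all transcripts, while the rank product called per2 and cry5 lower. Collection times are not given in the sources used here, so a response to the drug and an effect of collection cannot be told apart.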
